A study of Mus musculus with 16 samples.

How the data were processed

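RNA was sequenced from lineage-negative, Sca1-positive, Kit-positive (LSK) cells, the bone marrow fraction that holds haematopoietic stem cells and early progenitors, of mice with a DNMT3A R882H allele and of WT mice. Per the labels, donors were given poly(I:C) at 15 µg per g to switch on the allele through Mx1-Cre. The labels give a second poly(I:C) schedule too and do not say which animals had it. Donor marrow was taken 4 weeks later, mixed 1:1 with competitor marrow and transplanted into recipients. Recipients then received azacitidine, a nucleoside analogue that traps DNA methyltransferases on DNA, at 2.5 mg per kg, or 0.9% NaCl as vehicle, over 2 weeks with 5 days on and 2 off. The labels do not say whether donor cells were parted from competitor cells in the sort. RNA with a RIN under 8 was excluded by the authors, cDNA was amplified with a low-input kit, and inserts were about 200 bp long.

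The deposited count files hold raw counts per gene and per named repeat family, which the authors made with HISAT2 2.0.5 and featureCounts 1.6.2 on GRCm38, also called mm10. The length column of the deposited files is another unit, the number of bases in each counted feature. The deposited FPKM files hold the same counts divided by that length and by a single effective library size per library; in every library this ratio was constant across features. The labels name edgeR 3.26.6 and give no design, strand setting or rule for reads with several positions. Of 30141 gene identifiers, 30100 had a symbol and coordinates in the annotation. The remaining 1201 features were repeat families. The strand and multi-mapping settings behind the repeat counts are unknown, so these counts were compared between libraries only.

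The 16 libraries form 4 groups: 4 of WT with NaCl, 3 of WT with azacitidine, 4 of R882H with NaCl and 5 of R882H with azacitidine. Total counts ran from 35860445 to 56012766 per library. Levels are given in CPM, gene counts scaled by edgeR to the TMM-normalised library size, as mean ± SD. Amplified reads carry no molecular identifiers, and each SD or SE covers the spread between libraries. Pairs of libraries within a group were checked for duplicates; the lowest of 25 chi-square values per gene was 42.0, far from the value near zero that a copied library would give.

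Genes were kept by filterByExpr of edgeR 4.0.16 on the 4 groups, which left 18341. A quasi-likelihood model was fitted to all 16 libraries with 1 coefficient per group (R 4.3.3). The common dispersion was 0.166, a biological coefficient of variation of 40.7%. The contrasts were azacitidine against NaCl in each genotype, the difference between these responses, and R882H against WT under each treatment. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was a call. In libraries tested on simulated data, with 100 genes altered 2-fold and 100 altered 4-fold, the model recovered 7 to 24% of the former and 45 to 69% of the latter, depending on the contrast. The repeat families that passed the same filter, 1022 of them, were fitted in the same way with library sizes taken from the gene counts.

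A set of 35 gene lists was tested with camera at a preset correlation of 0.01 between genes, and again with a correlation estimated from the data (limma 3.58.1). They covered interferon-stimulated genes, nucleic acid sensing, antigen presentation, p53 targets, DNA damage repair, cell division, DNA replication, DNA methylation machinery, germline genes silenced by methylation, imprinted genes and retroelement-derived genes. Lineage lists were haematopoietic stem cell genes, lymphoid priming, neutrophil and monocyte priming, and megakaryocyte and erythroid priming. Markers of cells that the sort should exclude were mature B cells, plasma cells, T and NK cells, mature neutrophils, macrophages and dendritic cells, mast cells with basophils and eosinophils, and endothelial and stromal cells. Further lists were inflammatory NF-kB targets, immediate early genes, the integrated stress response, apoptosis regulators, azacitidine uptake and nucleotide metabolism, haem synthesis, cholesterol synthesis, glycolysis and hypoxia response, mitochondrially encoded genes, sex-linked genes, ribosomal protein genes, ribosome biogenesis and MYC core targets. Members were also adjusted over the list alone. The score of a list in a library is the mean log2 CPM of its tested members (prior count 2), compared between groups with exact two-sided permutation tests and adjusted over the lists.

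The contrasts, tests, thresholds, lists and the rule for naming genes were fixed before the data were examined. That rule took up to 10 called genes per direction with a mean log2 CPM of 1 or more, named gene models and pseudogenes aside, and whose groups did not overlap. It added up to 4 members with the lowest p of each list that was called or held a called member, and in every contrast a fixed set that included Dnmt3a, Dnmt1, Dnmt3b, Uhrf1, Kit, Ly6a, Mx1, Isg15, Ifit1, Irf7, Cdkn1a and Mki67. Some genes that this rule names are not reported here, and counts include them. Gm11837, Clec11a, Cd200r3 as an averaged effect and 4933406J09Rik fall outside it and were chosen after their values were seen. Effects averaged over genotypes or over treatments were added after seeing the data.

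The alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE size factors, no filter, a filter of 10 counts in 8 libraries, the replicate number as a block, the compared groups alone, a robust fit, a log2 fold limit of 1, and limma-trend on FPKM with 1 or 0.1 added. Each library was also left out in turn. Added after seeing the data were 1 to 3 surrogate variables (sva 3.50.0), a term parting replicate numbers 1 and 2 from the rest, fits without 2 or 3 doubted libraries, and a repeat total without rRNA. For the repeat families, all settings beyond the first model were unplanned, the fits without each library included. Whether equal replicate numbers mark related libraries was checked from residual correlations between the groups compared. For genotype under NaCl all 4 pairs exceeded the limit of 0.1, with correlations of 0.101 to 0.342, and 6 of 8 libraries matched best with their own number, so a blocked value stands beside that result. In no other contrast did every pair exceed it. No library was left out of the results described first.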

Results

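The transcriptomes of 16 LSK libraries were compared across genotype and treatment. There were 4 libraries of WT with NaCl (39303293 to 45429603 counts), 3 of WT with azacitidine (39862439 to 45011682), 4 of R882H with NaCl (35860445 to 48078144) and 5 of R882H with azacitidine (42412610 to 56012766). Repeat families, rRNA included, took 2.97 to 10.1% of the counts of a library. Immunoglobulin genes took 0.12 to 6.2% of gene counts, although the sort depletes mature lineages. Transcripts assigned to mouse Dnmt3a (ENSMUSG00000020661), the de novo methyltransferase whose mutated human version the R882H cells also carry, stood at 96.7 ± 9.84 CPM (SD, n = 4) in WT with NaCl. They stood at 90.5 ± 19.6 (n = 4) in R882H with NaCl, 105 ± 35.3 (n = 3) in WT with azacitidine and 96.2 ± 4.54 (n = 5) in R882H with azacitidine. No contrast called it in edgeR, with log2 differences of -0.13 to 0.12.

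Libraries numbered 1 and 2 stood apart from the others in 3 of the 4 groups, a split chosen after seeing the components, so no p is given for it. On the first principal component, which held 26.4% of the variance, they lay higher than the others of their group by 132 in R882H with NaCl, 85.5 in WT with NaCl and 73.1 in WT with azacitidine. The difference was 5.15 in R882H with azacitidine, where replicate 1 was the lowest, at -44.2. Ribosomal protein genes scored 8.80 ± 0.24 in the 4 NaCl libraries numbered 1 and 2 and 7.69 ± 0.18 in the 4 numbered 3 and 4. Megakaryocyte and erythroid genes scored 5.94 ± 0.62 against 4.54 ± 0.18, and neutrophil and monocyte genes 6.20 ± 0.28 against 5.63 ± 0.15. Haematopoietic stem cell genes scored 5.11 ± 0.44 against 5.93 ± 0.19, and retroelement-derived genes 0.98 ± 0.22 against 1.93 ± 0.13. Interferon-stimulated genes scored 4.26 ± 0.29 against 4.67 ± 0.06. The edgeR model called 5250 genes between these sets of NaCl libraries, 2830 higher and 2420 lower in numbers 1 and 2. The labels do not say what the numbers stand for. The second component set 1 library apart, R882H with NaCl replicate 1, in which the T cell receptor component Cd3d reached 22.3 CPM against 0.144 to 2.41 in its group.

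**Figure D1:**
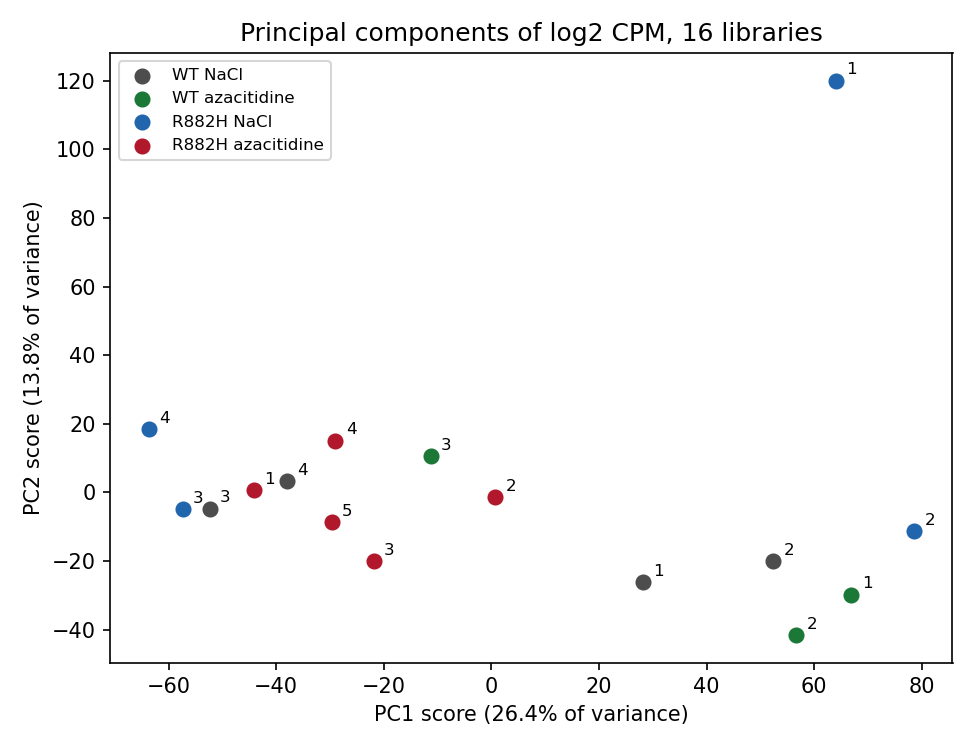
Scores of the 16 libraries on the first and second principal components of log2 CPM, in score units, with the percent of variance on each axis. Colours mark the 4 groups and digits the replicate number; R882H with NaCl replicate 1 lies at 120 on the second component and all others at or below 18.5.

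The first contrast asked which genes azacitidine changed in R882H cells. Gm11837 (ENSMUSG00000086587, chromosome 4, 14929908 to 14953030, an antisense transcript of no established function) fell from 3.59 ± 0.993 CPM (SD, n = 4) to 0.717 ± 0.14 (n = 5), a log2 change of -2.32. All 5 treated libraries lay below all 4 controls. The haemoglobin gene Hba-a1 stood at 78.1 ± 95.0 CPM with NaCl, 211 and 82.2 in replicates 1 and 2 and 3.21 and 16.2 in replicates 3 and 4, and at 4.36 ± 4.79 with azacitidine. The platelet integrin Itga2b stood at 189 ± 28.9 and 297 ± 30.5. Immediate early genes, switched on within minutes of a stimulus, had positive changes in 24 of 25 members, with a median of 0.85. They scored 3.345 and 2.86 in R882H with NaCl replicates 1 and 2, and 4.67 and 3.83 in replicates 3 and 4. Treated libraries scored 4.30 to 5.52, a range that includes control replicate 3. Btg2, an antiproliferative gene of this list, had a log2 change of 0.85 (SE 0.24), and Atf3, a stress-induced transcription factor, stood at 0.0984 ± 0.119 CPM and 1.74 ± 3.31. Treated replicate 2 held 7.65 CPM of Atf3 and the other 4 treated libraries 0.259 ± 0.175.

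Adjusted over the list alone, 15 of 33 megakaryocyte and erythroid genes passed, 14 lower and Itga2b higher, among them Hba-a1 and the carbonic anhydrase Car2. Of 23 T and NK cell genes, 10 passed, all lower, and of 15 mitochondrially encoded genes 14, all lower. Car2 had a log2 change of -0.98 (SE 0.27), the T cell gene Skap1 -2.46 (SE 0.70) and the respiratory chain gene mt-Co3 -1.62 (SE 0.48). None of these members passed over all genes tested. The controls carried much of the difference: R882H with NaCl replicate 1 held 3.49 as its T and NK cell score, against 1.13 in replicate 2 and -0.20 or less in replicates 3 and 4. Its mitochondrial score was 7.29, against 6.25, 4.73 and 4.29, and replicates 1 and 2 scored 6.27 and 6.64 for megakaryocyte and erythroid genes against 4.37 and 4.45. All 5 treated libraries, at 4.52 to 5.25, lay between these pairs, and the score difference was -0.62 (exact two-sided p = 0.365, adjusted p = 0.752). Adjusted over the list alone, macrophage and dendritic cell genes held 4 called members (Cd68 higher, and Slc40a1, Ccr9 and Xcr1 lower) and haem synthesis 2 (Cpox and Blvrb, lower). Apoptosis regulators held 1 (Bcl2a1b, lower). Mast cell genes held 3, the interleukin-33 receptor Il1rl1 lower and the proteases Cma1 and Tpsb2 higher, Cma1 at 1.52 ± 2.42 CPM after azacitidine. Treated replicate 1 held 5.78 CPM of Cma1 and 11.7 of Tpsb2, and the other 4 treated libraries 0.457 ± 0.533 and 0.739 ± 1.01.

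Over all 18341 genes, edgeR called 1, Gm11837 (adjusted p = 0.0307), with 1227 at an unadjusted p under 0.05. DESeq2 called 97 and limma-voom 125, of which 22 were shared. Camera called 16 of 35 lists. Immediate early genes (adjusted p = 1.1e-11), neutrophil and monocyte priming (0.00077), lymphoid priming (0.0028), plasma cells (0.004), glycolysis and hypoxia response (0.0041), antigen presentation (0.023), inflammatory NF-kB targets (0.023) and mast cells (0.045) ranked higher. Ribosomal protein genes (1.1e-13), mitochondrially encoded genes (2.3e-12), T and NK cells (1.9e-06), haem synthesis (0.00074), megakaryocyte and erythroid priming (0.0041), imprinted genes (0.028), MYC core targets (0.045) and ribosome biogenesis (0.049) ranked lower. The 16 ran from adjusted p = 0.55 with an estimated correlation to adjusted p = 0.80 with an estimated correlation. Of the 16, only immediate early, mitochondrially encoded and ribosomal protein genes kept their call without each of the 16 libraries in turn. Such fits cannot test a difference that 2 libraries carry together. Ribosomal protein genes scored 9.01 and 8.92 in R882H with NaCl replicates 1 and 2, and 7.60 and 7.52 in replicates 3 and 4. Every treated R882H library lay between these pairs, at 7.71 to 8.16. Without R882H with NaCl replicate 2, ribosome biogenesis (adjusted p = 0.00516) and MYC core targets (0.0676) turned positive, and lymphoid priming (0.395) and megakaryocyte and erythroid priming (0.974) lost their call. Without replicate 1 of that group T and NK cells turned positive (0.65). The immediate early score was higher by 1.23 (exact two-sided p = 0.0397, adjusted p = 0.694 over the lists). The edgeR call of Gm11837 ended, leaving 0 genes, without any 1 of the 9 R882H libraries or without WT with NaCl replicate 1, 2 or 3, and also in fits with no filter, with a replicate block, with the R882H libraries alone, with 2 surrogate variables and without the 2 doubted libraries. Without the 3 doubted libraries it ended as well, and 2 other genes were called.

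In WT cells, azacitidine was compared with NaCl to give the response without the mutation. Interferon-stimulated genes, the antiviral set that type I interferon induces, were lower in 62 of 72 members, with a median log2 change of -0.42. Ifit3, which binds viral RNA complexes, stood at 4.46 ± 1.38 CPM (SD, n = 4) with NaCl and 0.869 ± 0.804 (n = 3) with azacitidine, and Irf7, the transcription factor that amplifies interferon production, at 48.9 ± 5.39 and 25.7 ± 8.69. Neutrophil and monocyte priming genes were higher in 27 of 28 members, with a median of 0.85. The Fc receptor gene Fcgr3 stood at 9.91 ± 3.92 and 42.9 ± 36.7, and Ms4a3, a marker of granulocyte and monocyte progenitors, at 22.5 ± 13.9 and 108 ± 88.1. Cd200r3, an activating receptor of basophils and mast cells, stood at 0.0808 ± 0.0818 and 1.28 ± 0.327.

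Adjusted over the list alone, Ifit3 passed among interferon-stimulated genes, Irf7 among nucleic acid sensing genes, Fcgr3, Ms4a3, Igsf6 and Clec12a among 28 neutrophil and monocyte genes, and Cd200r3 among 16 mast cell genes. Clec12a had a log2 change of 1.08 (SE 0.33) and Cd200r3 of 3.94 (SE 0.60). Ifit1 had -1.27 (SE 0.42) and the cell cycle inhibitor Cdkn1a 0.68 (SE 0.31), neither past the threshold. The interferon score was 3.57 and 3.69 in WT with azacitidine replicates 2 and 1 and 4.47 in replicate 3, the level of the controls at 4.48 ± 0.25. The same pair of libraries held the higher myeloid scores, 6.74 and 7.36 against 6.01.

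Over all genes, edgeR called 0 (lowest adjusted p = 0.0656, Cd200r3), with 1104 at an unadjusted p under 0.05. DESeq2 called 53 and limma-voom 0. Without WT with azacitidine replicate 3, edgeR called 7. Camera called 9 lists: higher for neutrophil and monocyte priming (adjusted p = 1.1e-10), ribosomal protein genes (1.1e-10), mast cells (0.00025), mitochondrially encoded genes (0.011) and mature neutrophils (0.041), lower for interferon-stimulated genes (1.4e-15), DNA replication (0.0011), imprinted genes (0.0043) and mature B cells (0.015). They ran from adjusted p = 0.41 with an estimated correlation to adjusted p = 0.78 with an estimated correlation. Of the 9, only interferon-stimulated genes, neutrophil and monocyte priming and ribosomal protein genes kept their call without each library in turn. As in R882H, these fits cannot test a difference that a pair of libraries carries together. All 3 lists also separated the NaCl libraries by number, with numbers 1 and 2 shifted in the direction seen here for azacitidine. WT with azacitidine held replicates 1 to 3 and WT with NaCl replicates 1 to 4, so the groups were not balanced for number. The interferon score was lower by 0.57 with azacitidine (difference -0.57, exact two-sided p = 0.143, adjusted p = 0.625).

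**Figure D2:**
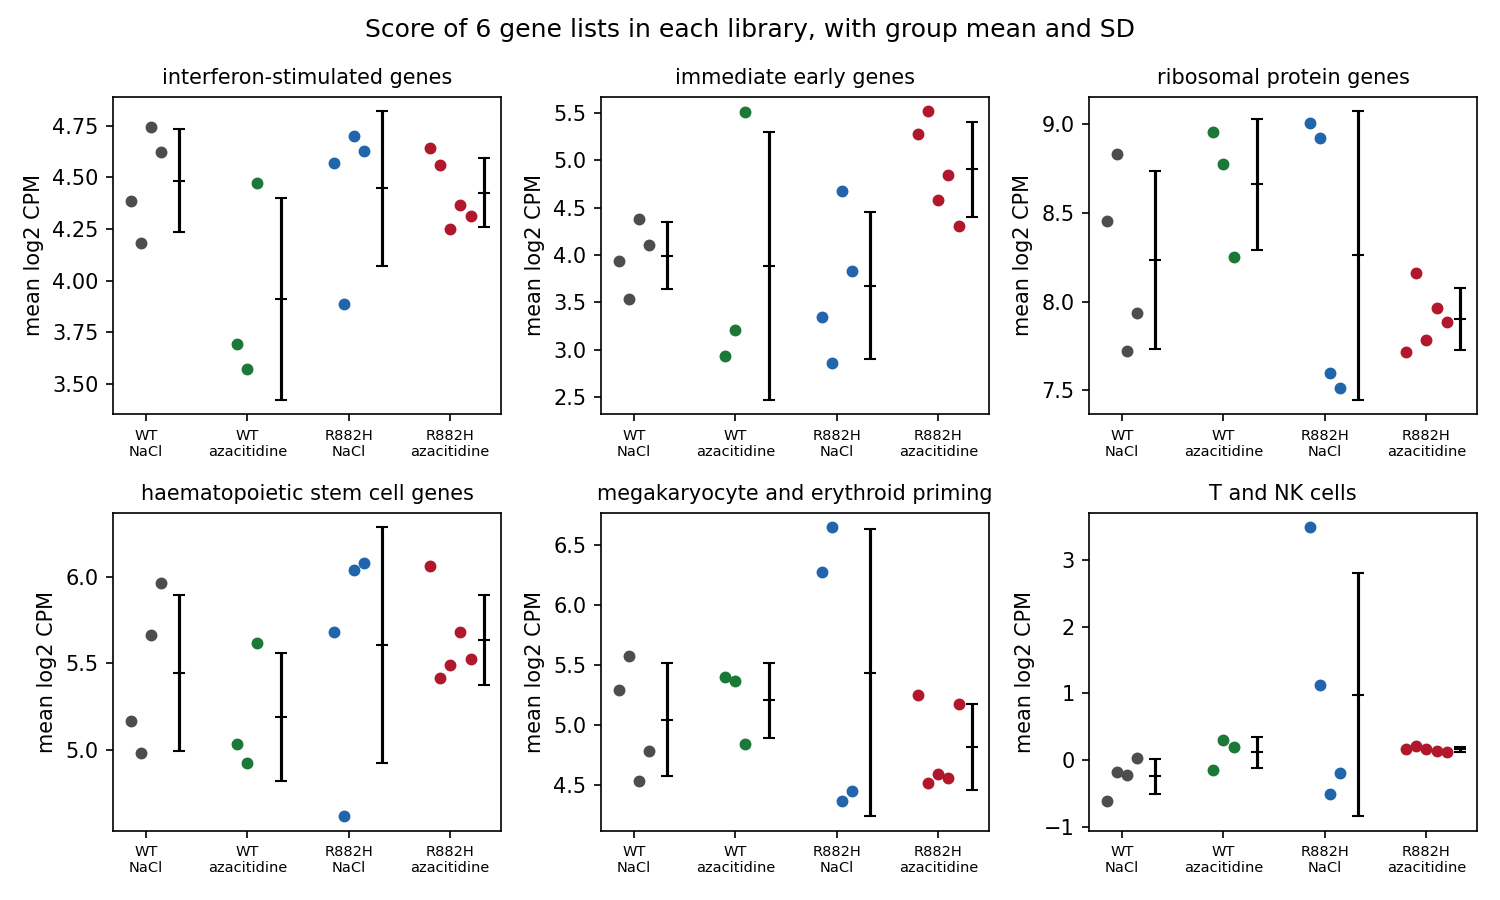
Mean log2 CPM of 6 gene lists in each library, 1 point per library, with the group mean and SD as bars. Interferon-stimulated genes averaged 3.91 in WT with azacitidine and 4.43 to 4.48 in the other groups, and the 4 R882H libraries with NaCl spread from -0.51 to 3.49 for T and NK cell genes.

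The difference between both azacitidine responses was tested directly, to see whether the mutation altered the response. Interferon-stimulated genes had a more positive response in R882H in 59 of 72 members, with a median log2 difference of 0.40. Irf7 gave 0.93 (SE 0.32) and Oas1g, a sensor of double-stranded RNA, 1.24 (SE 0.52). All 76 ribosomal protein genes had a more negative response in R882H, with a median of -0.88, and all 15 mitochondrially encoded genes, with a median of -1.92. Among lineage genes, 30 of 33 megakaryocyte and erythroid genes were negative (the haemoglobin gene Hbb-bt -2.28, SE 0.84), while 20 of 25 lymphoid priming genes were positive (the B cell transcription factor Ebf1 2.96, SE 1.22). The first 4 of these lists also separated libraries by number among the NaCl controls. Lymphoid priming stood at 5.09 ± 0.78 in numbers 1 and 2 and 5.15 ± 0.18 in numbers 3 and 4, but R882H with NaCl replicate 2 alone held 3.92. Without that library the difference in its score went from 0.69 (adjusted p = 0.554) to 0.38 (adjusted p = 0.625), and camera still called the list at the preset correlation (adjusted p = 0.0118). With all libraries it did not pass with an estimated correlation (adjusted p = 0.65 with an estimated correlation).

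Over all genes, edgeR called 0 (lowest adjusted p = 0.763), with 1114 at an unadjusted p under 0.05, DESeq2 called 12 and limma-voom 0. Adjusted over the list alone, 8 T and NK cell genes, 13 mitochondrially encoded genes and Cd200r3 passed, all negative. Camera called 14 lists. Interferon-stimulated genes (adjusted p = 1.4e-09), lymphoid priming (0.00033), immediate early genes (0.00033), glycolysis and hypoxia response (0.0022), inflammatory NF-kB targets (0.0037), plasma cells (0.0042), mature B cells (0.0048), DNA replication (0.0099) and nucleic acid sensing (0.015) were positive. Ribosomal protein genes (4.2e-23), mitochondrially encoded genes (8.5e-12), T and NK cells (4.2e-05), megakaryocyte and erythroid priming (0.00016) and neutrophil and monocyte priming (0.026) were negative. Without WT with azacitidine replicate 2 neutrophil and monocyte priming turned positive (adjusted p = 0.848), and without R882H with NaCl replicate 2 megakaryocyte and erythroid priming lost its call (0.125). The 7 lists that kept their call without each library in turn were interferon-stimulated, immediate early, mitochondrially encoded and ribosomal protein genes, lymphoid priming, inflammatory NF-kB targets and glycolysis and hypoxia response. Here too, a difference that a pair of libraries carries together was not tested by these fits. The 14 ran from adjusted p = 0.65 with an estimated correlation to adjusted p = 0.77 with an estimated correlation.

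Across genes, which are not independent replicates, the responses in both genotypes had a Pearson r of 0.0231, and 45% shared their sign. At an unadjusted p under 0.05, 85 genes were higher in both and 55 lower in both, where independence would give 16.4 and 16.6. Both contrasts came from the same fit and shared each gene's dispersion, so genes with a low estimate can pass in both. Overlaps in opposite directions were not counted, so the excess cannot show a shared response. An averaged azacitidine effect, added after seeing the data, called 4 genes in edgeR. Clec11a (ENSMUSG00000004473, chromosome 7), a secreted growth factor of bone marrow stroma and progenitors, rose from 9.31 ± 2.85 to 27.6 ± 14.3 CPM in WT (n = 4 and 3) and from 8.34 ± 1.45 to 21.3 ± 2.1 in R882H (n = 4 and 5), an averaged log2 change of 1.46 (adjusted p = 0.0148). Cd200r3 (ENSMUSG00000036172, chromosome 16) rose by 2.53 (adjusted p = 0.033) and reached 0.927 ± 0.543 CPM in R882H, against 0.429 ± 0.0463 with NaCl. The antisense transcript 4933406J09Rik (ENSMUSG00000107666, chromosome 6) rose by 2.47 (adjusted p = 0.00133), from 0.405 ± 0.118 to 2.63 ± 0.746 CPM in WT and from 0.467 ± 0.156 to 2.25 ± 0.74 in R882H. Gm11837 fell by 1.97 on the log2 scale (adjusted p = 0.0055), and in WT stood at 1.88 ± 0.455 and 0.606 ± 0.343 CPM. For all 4 genes every treated library lay beyond every control of its genotype, except Cd200r3 in R882H, where 1 treated library at 0.444 CPM lay within the controls. DESeq2 called 169 genes and limma-voom 117, with 62 in common. The azacitidine effect averaged over genotypes held 46 genes in edgeR without WT with azacitidine replicate 3, 23 and 9 without R882H with NaCl replicates 2 and 1, and 2 without R882H with NaCl replicate 3 or 4 or WT with NaCl replicate 4, where Clec11a and Cd200r3 were lost. Cd200r3 was kept in 6 of the 16 such fits, those without R882H with azacitidine replicate 2 or 5, R882H with NaCl replicate 1 or 2, WT with azacitidine replicate 3 or WT with NaCl replicate 3. With the replicate number as a block edgeR called 3 genes, Clec11a, 4933406J09Rik and Selp, while Gm11837 (adjusted p = 0.0593) and Cd200r3 (0.109) lost their call. Cd200r3 also lost it without R882H with NaCl replicate 1 and WT with azacitidine replicate 1 together (0.128), and without R882H with NaCl replicate 2 as well (0.0783). On FPKM with 1 added and no filter Cd200r3 (0.17) and Clec11a (0.0606) lost their call.

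**Figure D3:**
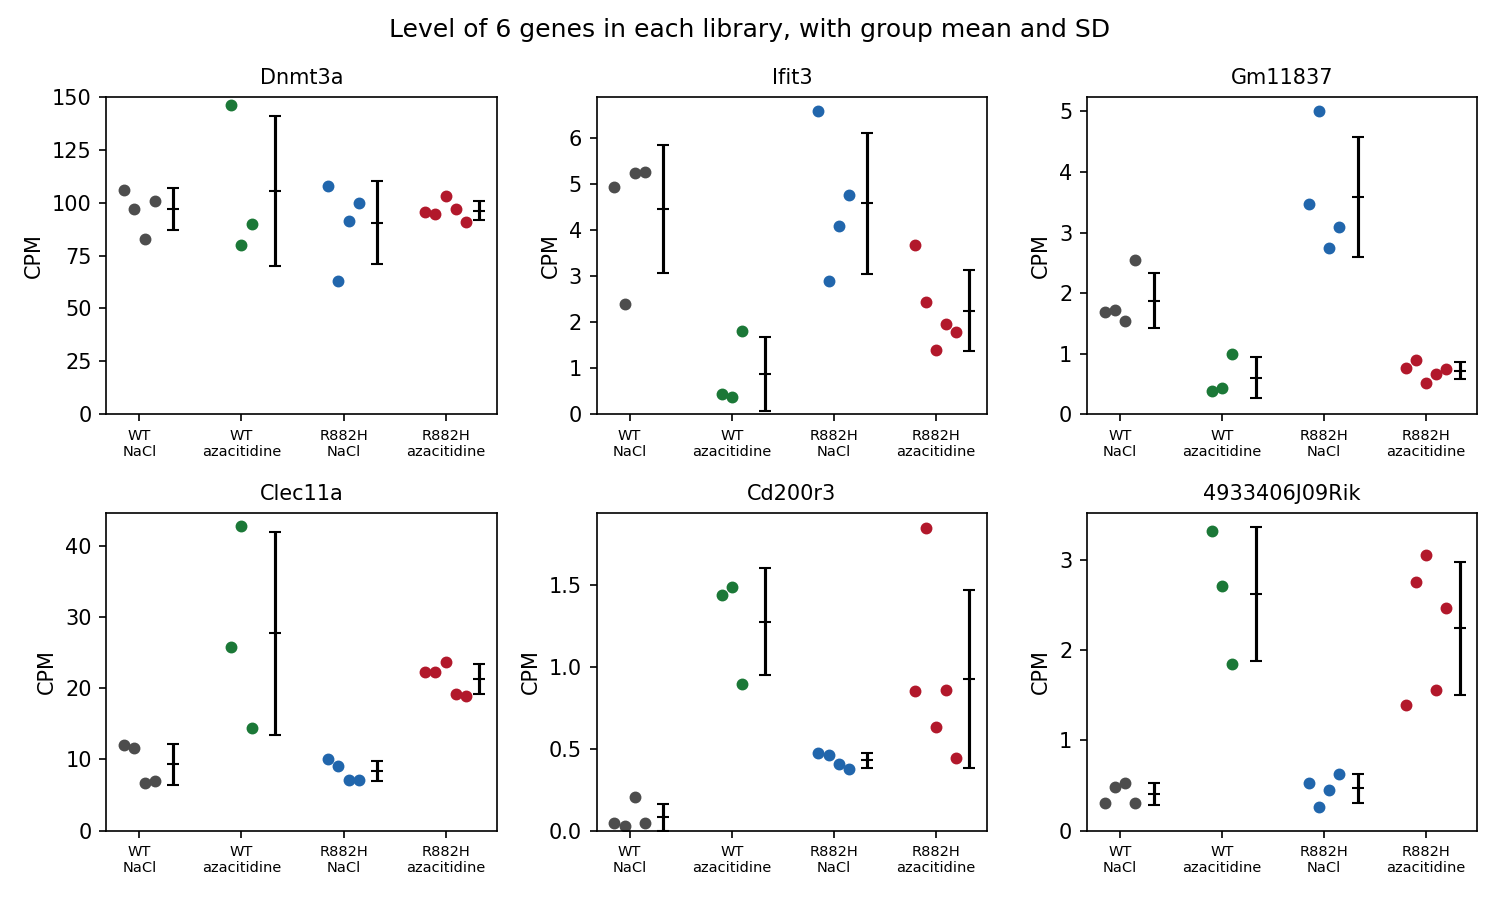
CPM of 6 genes in each library, 1 point per library, with the group mean and SD as bars. Ifit3 averaged 4.46 CPM in WT with NaCl and 0.869 in WT with azacitidine; 4933406J09Rik lay at 1.39 or higher in every library with azacitidine and at 0.624 or lower in every library with NaCl.

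R882H was compared with WT under NaCl to find differences between genotypes without the drug. Competitor cells may be part of both groups, as the labels do not say whether the sort parted them. T and NK cell genes were higher in 22 of 23 members, and 11 passed when adjusted over the list alone. Trac, the T cell receptor alpha constant region, stood at 0.241 ± 0.225 CPM in WT (SD, n = 4) and 8.58 ± 14.1 in R882H (n = 4), most of it in R882H replicate 1, and the T and NK cell score of replicates 3 and 4 was within that of WT. Lymphoid priming genes were lower in 19 of 25 members; the recombination gene Rag2 stood at 9.88 ± 2.75 and 4.85 ± 2.86, and Dntt, which adds nucleotides at antigen receptor junctions, at 490 ± 125 and 256 ± 137. R882H replicate 2 scored 3.92 for lymphoid priming, against 4.97 to 5.37 in the others of its group, and without it the score difference went from -0.56 (adjusted p = 1) to -0.25 (adjusted p = 0.952). Megakaryocyte and erythroid genes were higher in 24 of 33, the transferrin receptor Tfrc at 35.4 ± 14.7 and 115 ± 131. R882H replicates 1 and 2 held 103 and 305 CPM of Tfrc, and replicates 3 and 4 held 30.4 and 23.3, no more than WT at 25.2 to 56.6. Megakaryocyte and erythroid genes scored 6.27 and 6.64 in the former and 4.37 and 4.45 in the latter, with 4.53 to 5.57 in WT.

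In edgeR 1 gene was called, with 1026 at an unadjusted p under 0.05. DESeq2 called 28 and limma-voom 1, the latter shared. Adjusted over the list alone, Cd200r3 also passed (0.0808 ± 0.0818 CPM in WT). Camera called 9 lists. T and NK cells (adjusted p = 1.1e-08), megakaryocyte and erythroid priming (0.0014), haem synthesis (0.012), mast cells (0.013), mitochondrially encoded genes (0.013), cholesterol synthesis (0.034) and ribosome biogenesis (0.047) ranked higher, lymphoid priming (1.3e-06) and antigen presentation (0.032) lower. They ran from adjusted p = 0.52 with an estimated correlation to adjusted p = 0.83 with an estimated correlation. Without R882H with NaCl replicate 1 mitochondrially encoded genes changed sign (adjusted p = 0.209), and without replicate 2 so did haem synthesis (0.955) and ribosome biogenesis (0.0108). Megakaryocyte and erythroid priming lost its call without replicate 1 (0.186) or 2 (0.642), and T and NK cells without replicate 1 (0.213). Only lymphoid priming kept its call without each library in turn, at 0.00811 without R882H with NaCl replicate 2. With the replicate number as a block, edgeR called 1 gene, a different one. Leaving out 1 library left 0 genes, except WT with azacitidine replicate 2 or 3, as did fits with no filter, of the NaCl libraries alone and without the doubted libraries.

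The same genotypes were compared under azacitidine. All 76 ribosomal protein genes were lower in R882H, with a median of -0.77, and 51 had an unadjusted p under 0.05; Rps25 stood at 602 ± 279 CPM in WT (SD, n = 3) and 277 ± 17.1 in R882H (n = 5). All 15 mitochondrially encoded genes were lower, mt-Co3 at 14.8 ± 6.73 and 4.60 ± 1.05. Neutrophil and monocyte genes were lower in 25 of 28, the neutrophil protease Prtn3 at 740 ± 427 and 261 ± 24.4 and the granulocyte transcription factor Cebpa at 47.5 ± 25.9 and 22.9 ± 6.18. WT replicate 3 held 279 CPM of Prtn3 and 17.7 of Cebpa, and its score for these genes, 6.01, lay below all 5 R882H libraries at 6.04 to 6.48. Interferon-stimulated genes were higher in 58 of 72, with a median of 0.39, and stem cell genes in 30 of 35; Slamf1, a stem cell surface marker, stood at 15.1 ± 1.46 and 22.8 ± 10.2, with 40.5 in R882H replicate 1 and 18.4 ± 2.93 in the other 4. WT replicate 3 scored 4.47 for interferon-stimulated and 5.61 for stem cell genes, within R882H at 4.25 to 4.64 and 5.41 to 6.06, and WT replicates 1 and 2 scored 3.69 and 3.57, and 5.03 and 4.92. WT with azacitidine replicates 1 and 2 lay with the NaCl libraries numbered 1 and 2 on the first component, and held the highest ribosomal scores of both azacitidine groups.

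In edgeR 1 gene was called, with 1713 at an unadjusted p under 0.05. DESeq2 called 21 and limma-voom 1, the latter shared. Adjusted over the list alone, Prtn3 and the mitochondrial genes mt-Co2, mt-Atp6 and mt-Co3 passed, all lower. Camera called 14 lists. Interferon-stimulated genes (adjusted p = 8.1e-11), immediate early genes (0.00016), plasma cells (0.00025), stem cell genes (0.00057), nucleic acid sensing (0.0081), inflammatory NF-kB targets (0.012), glycolysis and hypoxia response (0.03), imprinted genes (0.033) and mature B cells (0.038) ranked higher. Ribosomal protein genes (2.2e-31), mitochondrially encoded genes (7.7e-10), neutrophil and monocyte priming (5.4e-05), mature neutrophils (0.025) and cell division (0.037) ranked lower. They ran from adjusted p = 0.69 with an estimated correlation to adjusted p = 0.88 with an estimated correlation. Of the 14, only interferon-stimulated, stem cell, mitochondrially encoded and ribosomal protein genes kept their call without each library in turn. A difference that a pair of libraries carries together was again not tested by these fits. The ribosomal protein score was lower by 0.76 (difference -0.76) and the mitochondrial score by 1.16 (difference -1.16), each at an exact two-sided p of 0.0179, the smallest that 3 against 5 allows (adjusted p = 0.156). The edgeR count was 0 when any 1 library was left out except R882H with NaCl replicate 1 or 2 or WT with azacitidine replicate 3, and with a replicate block or no filter.

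Averaged over both treatments, an effect added after seeing the data, edgeR called 1 gene between genotypes, also 1 after any 1 of the 16 libraries was left out; 1461 genes had an unadjusted p under 0.05, DESeq2 called 43 and limma-voom 1. Camera called 11 lists in none of the 5 contrasts. Their lowest adjusted p was 0.067 for macrophages and dendritic cells, 0.07 for germline genes silenced by methylation, 0.071 for DNA damage repair, 0.074 for azacitidine uptake and nucleotide metabolism, 0.092 for p53 targets, 0.097 for apoptosis regulators, 0.11 for DNA methylation machinery, 0.13 for retroelement-derived genes, 0.13 for the integrated stress response, 0.32 for sex-linked genes and 0.65 for endothelial and stromal cells. Dnmt1, the maintenance methyltransferase that azacitidine depletes as a protein, had a log2 change of 0.19 (SE 0.29) with azacitidine in R882H and -0.31 (SE 0.34) in WT.

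Repeat families were counted because loss of DNA methylation can derepress them. In WT, 989 of 1022 families were higher with azacitidine, with a median log2 change of 0.56, and all repeat counts together stood at 41581 ± 9667 CPM with NaCl (SD, n = 4) and 69598 ± 34383 with azacitidine (n = 3). In R882H they stood at 47887 ± 16361 with NaCl (n = 4) and 42064 ± 4254 with azacitidine (n = 5), with a median family change of -0.12, or 0.09 without R882H with NaCl replicate 1. The intracisternal A particle class, an active family of endogenous retroviruses, stood at 392 ± 52.3 and 530 ± 163 CPM in WT, and the mouse LINE-1 class, a retrotransposon with its own reverse transcriptase, at 1195 ± 360 and 1743 ± 921. WT with azacitidine replicate 1 held the highest share, 10.1% of its counts, and without it the median change in WT was 0.12. Repeat counts included rRNA, at 6013 ± 1655 CPM with NaCl and 18479 ± 16037 with azacitidine in WT, and 8336 ± 7416 and 4282 ± 1438 in R882H. The same replicate held 3.41% of its counts as rRNA, and the other 15 libraries 0.24 to 1.77%.

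No family was called in any contrast: edgeR gave 0, with 3 families at an unadjusted p under 0.05 for azacitidine in R882H, 154 for azacitidine in WT, 110 for the difference between them, 11 for genotype under NaCl and 135 for genotype under azacitidine. No other tool was run on them. Without WT with azacitidine replicate 2, 398 families were called for azacitidine in WT and 248 for genotype under azacitidine. Without replicate 1 of that group none were called, and the median went from -0.50 to -0.05 for genotype under azacitidine and from -0.67 to -0.23 for the difference between responses. Camera called 16 of 17 repeat classes higher in WT with azacitidine, 14 lower for the difference between responses, 14 lower for genotype under azacitidine, 9 higher for genotype under NaCl, without the drug, and 0 for azacitidine in R882H. With an estimated correlation it called 0 in each contrast (lowest adjusted p = 0.27 with an estimated correlation). The repeat total differed between genotypes under azacitidine by -27535 CPM (exact two-sided p = 0.0357), with azacitidine in WT by 28017 (p = 0.0857), in R882H by -5823 (p = 0.659) and between genotypes under NaCl by 6306 (p = 0.571); these 4 exact two-sided permutation tests were not adjusted. Without rRNA, a total added after seeing the data, the first of these differences was -13344 (exact two-sided p = 0.125), the second 15557 (p = 0.2), and the others -1772 (p = 0.817) and 3985 (p = 0.543). Without WT with azacitidine replicate 1, also chosen after seeing the data, the difference between genotypes under azacitidine was -7879 CPM, or -2853 without rRNA, and that with azacitidine in WT 8362, or 5067.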

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

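All tests of explanations in this part were chosen after the result was seen, except the test without immunoglobulin genes. Each group of 4 or 5 libraries was searched for a value far from the rest (Dixon's test at 95%). Of 135 such groups 8 held one, 5.93%, and chance alone gives about 1 in 20.

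Interferon-stimulated genes scored 3.89 in R882H with NaCl replicate 2, where the other libraries of the group lay at 4.57 to 4.70. Imprinted genes scored 2.03 in the same library, against 2.89 to 3.07. Germline genes silenced by methylation scored 0.78 (0.781) in WT with NaCl replicate 3, against 0.42 to 0.46. Mature neutrophil genes scored 4.26 in R882H with azacitidine replicate 2, against -1.88 to -0.61. Repeats took 6.81% of counts in R882H with NaCl replicate 1, against 3.72 to 3.9%. Immunoglobulin genes took 5.45% of gene counts in WT with NaCl replicate 3, against 0.46 to 1.02%, and 6.2% in R882H with azacitidine replicate 4, against 2.22 to 3.28%. Cd200r3 reached 0.203 CPM in WT with NaCl replicate 3, against 0.0267 to 0.047.

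A second search took every gene list whose azacitidine response differed between genotypes by camera on the interaction. There were 14, with adjusted p of 1.4e-09 for interferon-stimulated genes, 0.015 for nucleic acid sensing, 0.0099 for DNA replication, 0.00033 for lymphoid priming, 0.026 for neutrophil and monocyte priming and 0.00016 for megakaryocyte and erythroid priming. The others were mature B cells at 0.0048, plasma cells at 0.0042, T and NK cells at 4.2e-05, inflammatory NF-kB targets at 0.0037, immediate early genes at 0.00033, glycolysis and hypoxia response at 0.0022, mitochondrially encoded genes at 8.5e-12 and ribosomal protein genes at 4.2e-23. None passed with an estimated correlation (lowest adjusted p = 0.65 with an estimated correlation). As many lists were called in 50 of 100 splits of the libraries, with up to 23 in another split, so chance was not excluded.

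The first pattern weighed was the separation of libraries 1 and 2 from 3 and 4 under NaCl, in which ribosomal protein, mitochondrial and erythroid genes were higher and stem cell and macrophage genes lower in numbers 1 and 2. Total counts did not part the sets (exact two-sided p = 0.6), and without immunoglobulin genes edgeR still called 5344 genes, so library size and immunoglobulin reads were argued against. Mature cells of many types carried together would raise their markers together. Of 7 marker lists 3 were lower in numbers 1 and 2 by more than the pooled SD (mature B cells, macrophages and dendritic cells, endothelial and stromal cells) and 1 higher (mast cells), so this was not seen. Single cell types carried in single libraries, as with T cell genes in R882H with NaCl replicate 1, would not move all lists together, so they stay open. Also open is a batch of sorting, amplification or animals that the labels do not give, or a true difference in the share of erythroid progenitors within the LSK gate. No biological explanation was tested, as the design gives none for the numbers.

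The second pattern was the higher level of repeat families in WT with azacitidine, where 989 of 1022 families had a positive change. If loss of methylation acted on retroelements, endogenous retroviruses would exceed DNA transposons. Their mean change over families was smaller by the difference -0.0702 (log2, pooled SD 0.171, exact two-sided p = 0.6), and the LINE-1 classes differed from DNA transposons by -0.05 to 0.09. This argued against a rise particular to retroelements as the cause of the broad increase. The comparison cannot speak for single families or copies, because means over families dilute them and the rule for reads with several positions is unknown. The explanation stays open for 2 class totals. ETn and MusD changed by 0.413 beyond DNA transposons in WT (pooled SD 0.328, exact two-sided p = 0.0286), but by -0.0973 in R882H (pooled SD 0.648). That p is the smallest that 3 against 4 libraries allow, and was not adjusted over the classes and measures tested. The total of MuLV, VL30 and other class I retroviruses changed by 0.246 in WT (pooled SD 0.464) and by a similar 0.237 in R882H (pooled SD 0.266). The means over families of these classes differed in WT by -0.0907 and -0.0416. The family MMETn-int held most of the ETn and MusD counts, at 88.8 to 155 CPM in WT with azacitidine and 40.7 to 72.6 with NaCl. In R882H it stood at 76.9 to 120 with azacitidine, 137 and 302 in NaCl replicates 1 and 2, and 47.7 and 47.4 in replicates 3 and 4. A single library stays open: without WT with azacitidine replicate 1 the median fell from 0.555 to 0.118, still positive, while without replicate 2 it was 0.833 and 398 families were called. Reads from DNA or unspliced RNA stay open too. The share of gene counts in untested genes was 0.0624% in WT with azacitidine replicate 1, highest in repeats, and 0.0729% in R882H with NaCl replicate 1, second in repeats. It was 0.0305 to 0.0435% in the WT libraries with NaCl and at most 0.045% in the remaining libraries. The libraries with most repeats thus held the largest shares, though not in the same order, which does not decide the question.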

How the results depend on the processing

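The term for replicate numbers 1 and 2, the surrogate variables, the fits without doubted libraries, the repeat totals without rRNA or 1 library and both averaged effects were chosen after seeing the data. Refits of the repeat families, those without 1 library included, were not planned either. The doubted libraries were R882H with NaCl replicate 1 and WT with azacitidine replicate 1, to which the fit without 3 libraries added R882H with NaCl replicate 2. The FPKM settings were fitted with limma-trend, and the settings without another tool's name with edgeR. Unless stated, the cause of a difference between settings was not tested.

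For azacitidine in R882H edgeR called 1 gene, Gm11837, also with RLE factors, the stricter filter, a robust fit, the fold limit and 3 settings of FPKM. DESeq2 called 97 and limma-voom 125. The count was 0 with no filter, the replicate block, the R882H libraries alone, 2 surrogate variables and without 2 doubted libraries, where edgeR held 1227 genes at an unadjusted p under 0.05 in the first model. It was 2 with the number term, 2 with 1 surrogate variable, 12 with 3 and 2 without 3 doubted libraries, where the genes were Serpinf1 and Arhgef28 and Gm11837 lost its call. Leaving out 1 library gave 0 to 1, with 1 only without any WT with azacitidine library or WT with NaCl replicate 4.

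For azacitidine in WT edgeR and limma-voom called 0 (1104 at an unadjusted p under 0.05), DESeq2 53, FPKM + 0.1 gave 1, FPKM + 1 with no filter 1 and 3 surrogate variables 2; leaving out 1 library gave 0 to 7, the highest without WT with azacitidine replicate 3. For the difference between responses DESeq2 called 12 and FPKM + 0.1 gave 1, while edgeR in all its settings and with any library left out, limma-voom and FPKM + 1 called 0 (1114 at an unadjusted p under 0.05).

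For genotype under NaCl edgeR called 1 gene, as did limma-voom, RLE, the stricter filter, a robust fit and 1 surrogate variable. DESeq2 called 28, the number term gave 2 and 3 surrogate variables 2. The replicate block also gave 1, a different gene. The count was 0 with the fold limit, no filter, the NaCl libraries alone, 3 settings of FPKM, 2 surrogate variables and without 2 or 3 doubted libraries (1026 at an unadjusted p under 0.05 in the first model). Leaving out 1 library gave 0 to 1, with 1 only without WT with azacitidine replicate 2 or 3. For genotype under azacitidine edgeR called 1 gene and DESeq2 21. Limma-trend gave 0 on FPKM + 1 with and without a filter, and on FPKM + 0.1 it called 1 different gene, Ighd1-1. The edgeR count was 0 with the fold limit, no filter, the block, the azacitidine libraries alone, a robust fit, the number term, 1 or 2 surrogate variables and without 2 or 3 doubted libraries (1713 at an unadjusted p under 0.05). Leaving out 1 library gave 0 to 1, with 1 only without R882H with NaCl replicate 1 or 2 or WT with azacitidine replicate 3.

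The azacitidine effect averaged over genotypes held 4 genes, 169 by DESeq2, 117 by limma-voom, 3 with the replicate block, 3 with the filtered FPKM settings, 2 with FPKM + 1 and no filter, 14 with the number term, 67, 105 and 130 with 1, 2 and 3 surrogate variables and 18 without 3 doubted libraries. Leaving out 1 library gave 2 (without R882H with NaCl replicate 3 or 4 or WT with NaCl replicate 4) to 46 (without WT with azacitidine replicate 3). The averaged genotype effect held 1 gene, 0 with the fold limit, 43 by DESeq2 and 2 with 2 surrogate variables.

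With an estimated correlation camera called 0 lists in each of the 5 contrasts, and 62 list calls ended. Leaving out 1 library gave 7 to 14 lists for azacitidine in WT (highest without WT with azacitidine replicate 3), 7 to 14 for genotype under NaCl (highest without R882H with NaCl replicate 2) and 8 to 15 for genotype under azacitidine (lowest without WT with azacitidine replicate 1). Of 175 list values 20 fits without 1 library reversed a direction that was past the threshold in either fit.

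For azacitidine in R882H the adjusted p across such fits ran, for lists reversed without R882H with NaCl replicate 2, from 0.00191 to 0.914 for interferon-stimulated genes, 9.57e-07 to 0.982 for cell division, 0.000102 to 0.918 for stem cell genes, 1.65e-05 to 0.19 for ribosome biogenesis and 0.00226 to 0.178 for MYC core targets. Without R882H with NaCl replicate 1 the T and NK cell list turned positive (0.65, range 6.61e-10 to 0.65), and DNA damage repair (0.0191, range 0.000809 to 0.859) and DNA replication (0.0334, range 2.89e-05 to 0.995) turned negative. Without R882H with azacitidine replicate 2 mature neutrophils turned negative (7.05e-05, range to 0.779). The reversed values without R882H with NaCl replicate 2 were 0.00516 for ribosome biogenesis and 0.0676 for MYC core targets.

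For azacitidine in WT immediate early genes turned negative without WT with azacitidine replicate 3 (0.000584, range 0.000227 to 0.954). For the difference between responses, neutrophil and monocyte priming turned positive without WT with azacitidine replicate 2 (0.848, range 6.5e-06 to 0.848). Without R882H with NaCl replicate 2 cell division (0.0241, range 0.00648 to 0.973), ribosome biogenesis (0.000774, range to 0.992) and MYC core targets (0.0328, range to 0.994) turned positive. For genotype under NaCl, all of these turned negative without R882H with NaCl replicate 2: haem synthesis (0.955, range 2.64e-05 to 0.955), ribosomal protein genes (0.00641, range 1.52e-06 to 0.466), ribosome biogenesis (0.0108, range 7.37e-05 to 0.131) and MYC core targets (0.00128, range to 0.932). Without R882H with NaCl replicate 1 mitochondrially encoded genes (0.209, range 2.38e-07 to 0.209) and ribosomal protein genes (0.000688) turned negative.

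Of 10212 values of named genes across settings, 310 changed sign without ever passing the threshold and were not counted as reversed. DESeq2 put 18 named genes past the threshold that edgeR did not, limma-voom 3, and fits without 1 library ended 52 calls and added 6. The correlation of both azacitidine responses was -0.117 among genes with a mean log2 CPM of 3 or more and ran from -0.0566 (without R882H with NaCl replicate 4) to 0.125 (without WT with azacitidine replicate 1). Repeat families called by edgeR ran from 0 to 398 for azacitidine in WT and from 0 to 248 for genotype under azacitidine, both highest without WT with azacitidine replicate 2; the first model held 154 and 135 at an unadjusted p under 0.05. At the depth of these libraries, and with the dispersion estimated for each gene, simulated 2-fold changes were recovered in 7 to 24% of cases. The common biological coefficient of variation was 40.7%. The simulated libraries were drawn independently and did not carry the separation by replicate number. Depth and spread were not tested apart.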

Other observations

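All tests of explanations and splits in this part were chosen after the result was seen, except the free splits of the averaged effects, which were set down before their outcome was known.

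Genes called by both DESeq2 and limma-voom for the azacitidine effect averaged over genotypes were listed after seeing the data; there were 62, 31 higher and 31 lower. Beyond the 4 that edgeR also called, the higher ones included Mybpc3, a sarcomere protein (log2 change 1.23, SE 0.20), Lat2, a signalling adaptor of mast and B cells (0.94, SE 0.16), the platelet adhesion molecule Selp (1.38, SE 0.24), the galectin Lgals1 (1.22, SE 0.26) and Xlr4a (0.73, SE 0.18) and Xlr4c (1.29, SE 0.28), X-linked genes of which one is imprinted in mouse. The lower ones included Ifit3 (-1.69, SE 0.34), the chemokine receptor Ccr9 (-1.62, SE 0.37), the matrix protease Mmp2 (-1.12, SE 0.29), Serpinf1 (-1.26, SE 0.32) and Dpp4 (-0.64, SE 0.17). In edgeR their adjusted p ran from 0.0572 upward. Ifit3 was low with azacitidine in R882H too, at 2.25 ± 0.879 CPM (n = 5) against 4.59 ± 1.54 (n = 4), while Irf7 stood at 42.3 ± 8.83 and 42.3 ± 10.1.

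Other splits of the same libraries were fitted with edgeR to see how many genes a random grouping calls. For azacitidine in R882H, 6 of 100 splits called as many as the real 1 (highest other 3), and for genotype under azacitidine 3 of 56 as many as the real 1 (highest other 2), so chance was not excluded for either. For azacitidine in WT 35 of 35 called as many as the real 0 (highest other 2), and for the difference between responses 100 of 100 as many as the real 0 (highest other 4805). Every split reaches 0, so these counts decide nothing. They stand beside 1104 and 1114 genes at an unadjusted p under 0.05, and 53 and 12 called by DESeq2. For genotype under NaCl equal numbers were treated as pairs because of their residual correlations, though the labels do not say what the numbers mean. There 2 of 35 splits called as many as the real 1. The other of them kept all 4 pairs together, called 5250 genes and set numbers 1 and 2 against 3 and 4, which points to a structure of the libraries. Of the 8 splits that part all 4 pairs the real one called 1 and the other 7 called 0, and 8 are too few for a share under 0.05; with the number as a block 1 gene was called, Clca3a1. For the averaged azacitidine effect 3 of 100 splits called as many as the real 4 (highest other 696). These free splits took no account of the separation by replicate number, and the effect was added after seeing the data, so chance was not excluded. For the averaged genotype effect 1 of 100 free splits, the real one, called as many as the real 1 (highest other 0). Among 100 splits that part all 4 NaCl pairs 5 called as many (highest other 1), so chance was not excluded.

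The same count for gene lists by camera gave 50 of 100 splits with as many as the real 16 for azacitidine in R882H (highest other 21) and 27 of 35 with as many as the real 9 for azacitidine in WT (highest other 16). It gave 13 of 56 with as many as the real 14 for genotype under azacitidine (highest other 16). Chance was excluded for none of these 3. For genotype under NaCl 32 of 35 gave as many as the real 9 (highest other 22), and the 7 other splits that part all 4 pairs gave 11 to 16, again too few for a share under 0.05. Averaged effects called 13 lists for azacitidine and 15 for genotype, and 0 of each with an estimated correlation (lowest adjusted p = 0.29 with an estimated correlation for the former and adjusted p = 0.74 with an estimated correlation for the latter).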
